A study of Nothobranchius furzeri with 10 samples.

How the data were processed

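Skin of the turquoise killifish Nothobranchius furzeri, a short-lived freshwater fish, was profiled by RNA sequencing in 10 libraries. All came from males of the strain MZM-0410p at 27 weeks of age, per the labels. Total RNA was turned into libraries with a TruSeq RNA kit, per the labels' protocols. The labels place 5 libraries in a DMSO group (the solvent control) and 5 in a group given 15 pM rotenone, an inhibitor of mitochondrial complex I. They give no batch, day, treatment length or pairing, and replicate numbers follow the order of deposition and serve only as names. The labels do not say that each library came from a separate fish, so p-values measure the spread between these libraries.

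The authors deposited a table of raw read counts per gene and a table of RPKM values for the same 26739 gene identifiers. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4. The genome build, the annotation release, the strandedness of counting and the treatment of multi-mapping reads are not given in the sources used here, so overlapping genes and near-identical copies can share or lose reads. The kit does not mark strand, so reads of a gene and of an antisense partner cannot be told apart.

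The deposited RPKM values were compared with the counts before use. An RPKM value should equal the count divided by the gene length and by the library's own total. The length implied in this way was computed per library for the 4793 genes with at least 500 counts and an RPKM above 1 in every library, and the coefficient of variation (CV) over the 10 libraries was taken per gene. Gene lengths were then recovered from both tables. The counts as deposited were used for every main result. Beyond this comparison, the deposited RPKM entered the alternatives planned for them and the recovered gene lengths. Those lengths were used in the tests of gene length and in the recomputed RPKM.

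The identifiers carry no gene names. Of the 26739 identifiers, 0 matched a locus tag, synonym or accession in the RefSeq gene table of the assembly NfurGRZ-RIMD1, so no symbol was assigned. The 40 gene lists written beforehand (respiratory complexes, stress responses, skin, pigment, immune, muscle and blood cell types among them) could not be matched, and 0 of them were tested. The rule for the genes to name required a symbol. It was replaced by its own fallback, the smallest p in each direction, limited to 2 identifiers that were lower and 2 that were higher.

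Genes were filtered with filterByExpr (minimum count 10, smallest group 5), which kept 18435 genes holding 99.9% of all reads, and 4007 genes had no read in any library. Libraries were scaled with TMM and tested with edgeR 4.0.16 (glmQLFit with robust=TRUE and glmQLFTest, a quasi-likelihood F test) in R 4.3.3, rotenone against DMSO, with no covariate. P-values were adjusted by Benjamini-Hochberg at a threshold of 0.05, two-sided. The standard error of a log2 fold change was its size divided by the square root of F, and 95% intervals used the test's total degrees of freedom. Normalised read counts are TMM-scaled CPM, counts relative to the scaled library total. The separation of whole profiles was the share of squared Euclidean distance on log2 CPM (prior count 2) that lay between the groups, with a one-sided exact permutation test over all 252 assignments. Differences of 8 library measures were tested by two-sided exact permutation and adjusted by Benjamini-Hochberg over the 8. These measures were chosen after the totals and scaling factors had been seen.

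Alternatives chosen before the data were examined were other scalings (RLE, upper quartile, library size), no count filter and a mean of at least 50 counts, DESeq2 1.42.0, limma 3.58.1 (voom, with and without quality weights), robust=FALSE, 1 surrogate variable (sva 3.50.0), limma-trend on log2 of the deposited RPKM with pseudocounts of 1 and 0.1 and with a mean RPKM of at least 1, an adjusted p under 0.1, the 500 most variable genes, and each library left out in turn. Alternatives added after the data were seen were RPKM recomputed with each library's own total, DESeq2 with TMM factors, 2 surrogate variables, DESeq2 with each library left out, and other definitions of the most abundant genes.

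The tests were checked on simulated counts drawn from the means, dispersions and library sizes of these 10 libraries, with 200 genes changed. The changed genes were drawn only from those above a floor of mean expression, so recovery of scarcer genes was not measured. At 4-fold, edgeR recovered 91.0% of 67 changed genes and DESeq2 97.0%, and at 2-fold they recovered 32.8% and 59.7% of 67. The adjusted threshold also depends on how many genes change, so these shares are not the power of the tests in the real data. False calls numbered 4 among the 18286 genes edgeR tested and 26 among the 18435 genes given to DESeq2. Each gene was drawn independently of the others, so differences between libraries shared by many genes were absent from the simulation. Total counts ranged from 18801139 to 42253397 per library. No pair of libraries within a group was a repeat of one library: the lowest median chi-square per gene was 4.42, against 0.455 from counting noise alone.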

Results

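The skin transcriptome was measured in 5 libraries from fish given 15 pM rotenone and 5 from fish given DMSO. Rotenone blocks complex I, the entry point of electrons from NADH into the mitochondrial respiratory chain, and the comparison asks whether exposure to a picomolar dose alters gene expression in the skin of 27-week-old males. Total counts per library ranged from 21415012 to 42253397 in the DMSO group and from 18801139 to 33406901 in the rotenone group. Between 20885 and 21715 genes had at least 1 read in a library. Neither total counts (two-sided exact permutation p = 0.87, adjusted 0.87 over 8 library measures) nor the number of detected genes (exact permutation p = 0.60, adjusted 0.79) differed between the groups beyond the spread of the libraries.

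Whole profiles of rotenone and DMSO skin were not set apart beyond the spread between libraries. The share of squared distance that lay between the groups was 11.7%, against a mean of 11.1% over all 252 assignments of the libraries (one-sided exact permutation p = 0.33, where 0.0079 is the smallest value possible). Without DMSO replicate 2 the share was 19.7%, which is 7.23 percentage points above the mean over assignments of those 9 libraries (exact permutation p = 0.11). Correlations of log2 CPM across the tested genes ran from 0.893 to 0.972 within the DMSO group, from 0.906 to 0.964 within the rotenone group and from 0.882 to 0.970 between the groups. These are correlations across genes, which are not independent replicates. The first principal component held 37.5% of the variance. DMSO replicate 2 had the highest score on it at 86.2, followed by rotenone replicates 5 (58.5), 3 (56.2) and 4 (24.0), and the other 6 libraries of both groups lay between -48.6 and -25.8. Group means on this component were -12.4 ± 55.7 for DMSO and 12.4 ± 48.3 for rotenone (SD, n = 5 each, exact permutation p = 0.49, adjusted 0.79).

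**Figure D1:**
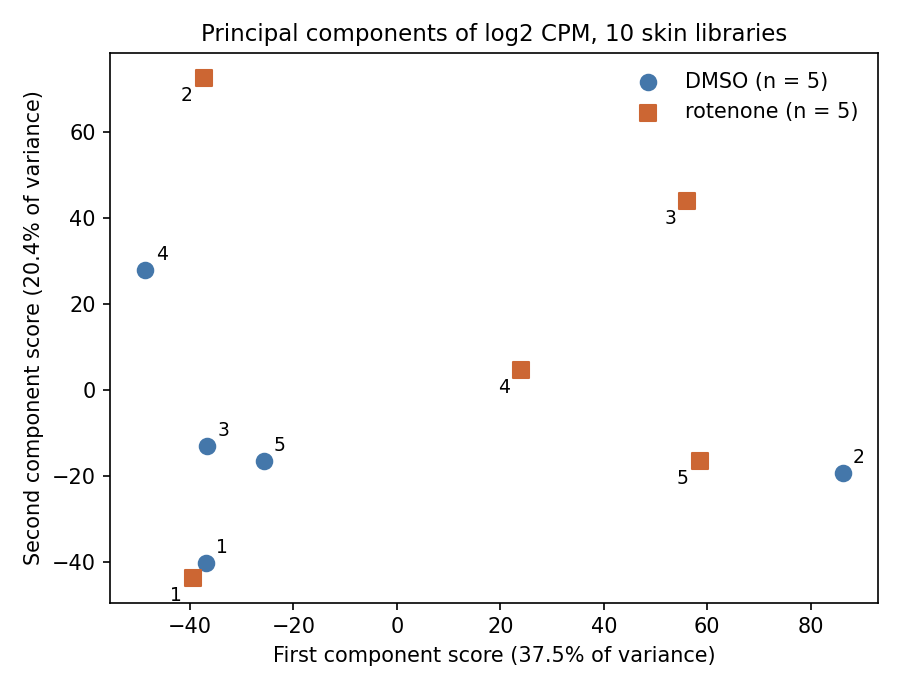
Principal component scores of the 10 skin libraries from log2 CPM, with the first component (37.5% of variance) on the x axis, the second (20.4%) on the y axis, and replicate numbers beside the points (circles, DMSO, n = 5; squares, rotenone, n = 5). DMSO replicate 2 lies with rotenone replicates 3, 4 and 5 at scores above 0 on the first component, and rotenone replicates 1 and 2 lie with the other DMSO libraries below 0.

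No gene was called as changed by rotenone at an adjusted p under 0.05 with edgeR's quasi-likelihood test: 0 of 18435 genes passed, with a smallest adjusted p of 0.078. At an unadjusted p under 0.05 the same test gave 1412 genes, 688 higher and 724 lower in rotenone skin, against 922 expected by chance. Of 100 splits of the 10 libraries into 5 and 5, 23 reached 1412, the real one included, so chance assignment is not excluded. When libraries were scaled by their totals alone, the unadjusted genes were 267 higher and 1531 lower, and 18 genes, all lower, passed an adjusted p under 0.05. At an adjusted p under 0.1 the edgeR test with TMM scaling gave 23 genes, of which 20 were lower and 3 higher. DESeq2 on the same counts called 231 genes at an adjusted p under 0.05, 57 higher and 174 lower, and all 23 of the edgeR genes were among them. With TMM factors and the edgeR filter DESeq2 called 232 genes, 81 higher and 151 lower. Its count depended on single libraries: it was 133 without DMSO replicate 1, 151 without DMSO replicate 5, 375 without rotenone replicate 1, and 626 (338 higher, 288 lower) without DMSO replicate 2. Limma called 1 gene with voom and 26 with voom and library quality weights.

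For each of the 4 genes named here, 2 with the smallest p in each direction, the 5 rotenone values lay on one side of the 5 DMSO values, and none passed an adjusted p under 0.05 in edgeR with TMM scaling. The genes were picked for their p in these libraries, so the lack of overlap describes them and tests nothing. Nfu_g_1_021435 had the smallest p. Its normalised read count was 525 ± 56.3 CPM in DMSO skin and 128 ± 48.4 CPM in rotenone skin (SD, n = 5 each), and its values in all 5 rotenone libraries (79.6 to 187 CPM) lay below those in all 5 DMSO libraries (461 to 582 CPM). This is a log2 fold change of -2.03 ± 0.25 (SE), or 4.09-fold lower in rotenone, with an edgeR adjusted p of 0.078 and a DESeq2 adjusted p of 2.7e-12. Over all alternative fits its adjusted p ran from 2.7e-12 to 0.44, the highest with deposited RPKM. Nfu_g_1_004690 was 3.06-fold lower, at 1.39 ± 0.34 CPM against 4.23 ± 0.49 CPM (log2 fold change -1.61 ± 0.21, edgeR adjusted p = 0.078). It rested on 24 to 165 counts per library. With library-size scaling both genes passed in edgeR, at adjusted p = 0.012 for Nfu_g_1_021435 and 0.031 for Nfu_g_1_004690. That scaling moved the median log2 fold change of all tested genes from 0.03 to -0.11, which favours genes that were lower. Among genes that were higher, Nfu_g_1_006811 stood at 18.5 ± 2.48 CPM in rotenone skin and 10.5 ± 0.98 CPM in DMSO skin, a 1.76-fold difference (edgeR adjusted p = 0.095). Nfu_g_1_003916 stood at 12.8 ± 0.85 CPM against 6.59 ± 1.31 CPM, a 1.94-fold difference (edgeR adjusted p = 0.097). On the log2(RPKM + 1) scale 3 of the log2 fold changes were smaller. They were -0.73 with deposited and -0.86 with recomputed RPKM for Nfu_g_1_004690, 0.48 and 0.70 for Nfu_g_1_003916, and 0.68 and 0.49 for Nfu_g_1_006811. With a pseudocount of 0.1 the deposited RPKM gave -1.35, 0.55 and 0.92 for these genes. The identifiers are given as deposited, since no gene name or position could be attached to them here.

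**Figure D2:**
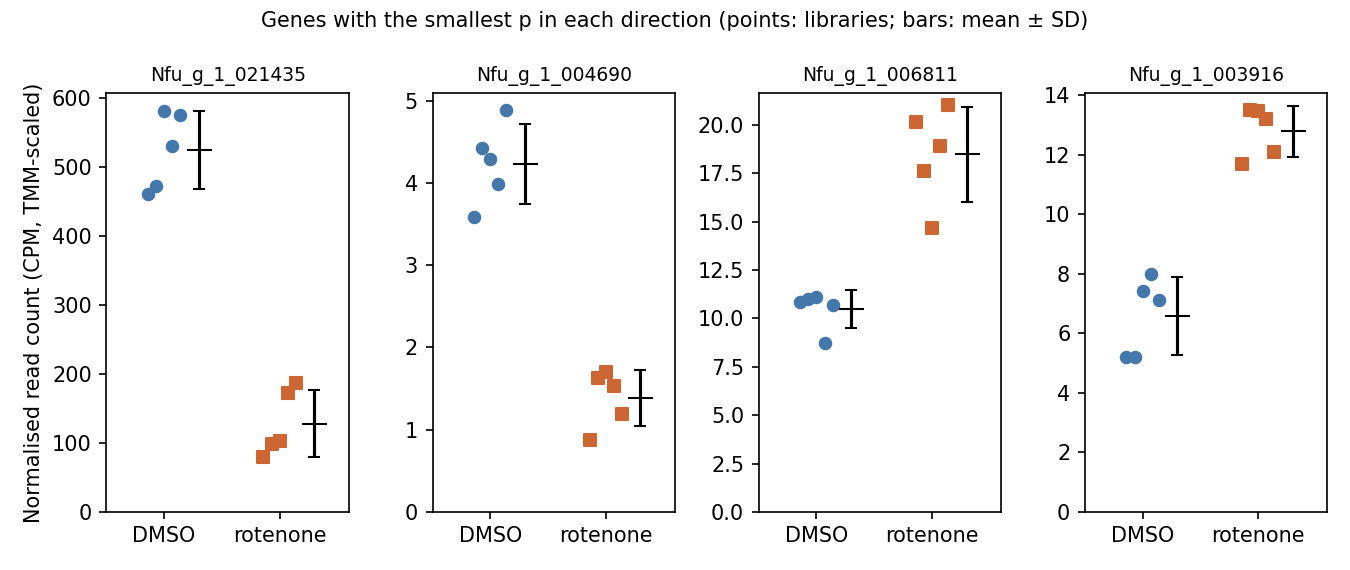
Normalised read counts (TMM-scaled CPM, linear axes from 0) of the 2 genes with the smallest p among those lower and the 2 among those higher in rotenone skin, with 1 point per library (circles, DMSO; squares, rotenone) and a bar for the mean ± SD of 5 libraries. Nfu_g_1_021435 falls between 461 and 582 CPM in the DMSO libraries and between 79.6 and 187 CPM in the rotenone libraries.

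The measured differences were small for most genes. The median size of the log2 fold change was 0.17, and 90% of genes stayed under 0.59 and 99% under 1.43 in size. For 13162 of the 18435 genes (71.4%) the 95% interval of the edgeR fold change excluded a 2-fold change in either direction. The 5 rotenone values lay wholly above or wholly below the 5 DMSO values in 327 genes (1.77%), 135 higher and 192 lower. A random assignment of the libraries would give 0.794%, or 146 genes, on average if the libraries were exchangeable. Single assignments vary widely around that mean: of 100 splits into 5 and 5, 9 reached 327, the real one included, and the highest other gave 623. Chance assignment is therefore not excluded.

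Reads were more concentrated on the most abundant genes in rotenone skin. The 100 genes with the highest mean share took 37.7 ± 3.66% of reads in rotenone libraries and 32.1 ± 1.73% in DMSO libraries (SD, n = 5 each). All 5 rotenone libraries (34.8% to 43.6%) lay above all 5 DMSO libraries (29.7% to 34.4%), with a two-sided exact permutation p of 0.0079, the smallest this design allows, and 0.032 after adjustment over the 8 library measures. The measures were chosen after the scaling factors of these libraries had been seen, and the adjustment does not cover that choice. The 10 most abundant genes took 15.6 ± 2.11% of reads in rotenone libraries (SD, n = 5), 3.07 percentage points more than in DMSO libraries (exact permutation p = 0.0079, adjusted 0.032), while the single most abundant gene took 2.57 ± 1.27% against 2.86 ± 1.02% (exact permutation p = 0.70, adjusted 0.80). The TMM scaling factor, which falls when a few genes take more of the reads, was 0.954 ± 0.078 in rotenone and 1.05 ± 0.046 in DMSO libraries (exact permutation p = 0.048, adjusted 0.13). Of the 100 genes, 39 had a higher mean share of reads in rotenone libraries, while 88 had an edgeR log2 fold change above 0 after TMM scaling (median 0.12), as did 10216 of all 18435 tested genes (median 0.03). TMM scaling moved the median of all genes by 0.14 relative to library-size scaling, so the number above 0 depends on the scaling. The 10 largest rises summed to 5.02 percentage points, and the other 90 genes together differed by 0.52 points. These 10 genes were picked for their rise in these libraries, so a small remainder follows from the choice. They took 11.3% to 17.1% of reads in rotenone replicates 2 to 5, but 4.82% in rotenone replicate 1, against 4.87% to 8.25% in DMSO libraries. None of the 100 passed an adjusted p under 0.05 in edgeR (0 genes), and DESeq2 called 2.

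The deposited RPKM values were compared with the counts in the 4793 genes that had at least 500 counts in every library and an RPKM above 1. With each column's own total, the gene length implied by the 2 tables varied between libraries with a median CV of 31.4% over these genes. With the 10 library totals assigned in a cycle running down the rows and on into the next column, the median CV was 0.0019%, and 99.1% of the recovered lengths were within 0.3 of a whole number of bases. The other 9 starting points of the cycle gave median CVs of at least 29.4%. If the cycle held for the whole table, 9.97% of the values above 0 were divided by their own library's total, the factors off ranged from 0.445 to 2.25, and 20.1% of the values above 0 were off by more than 1.5-fold. The sign of the difference between group means, on the log2(RPKM + 1) scale, differed between deposited and recomputed RPKM in 3966 of 18435 genes (21.5%).

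**Figure D3:**
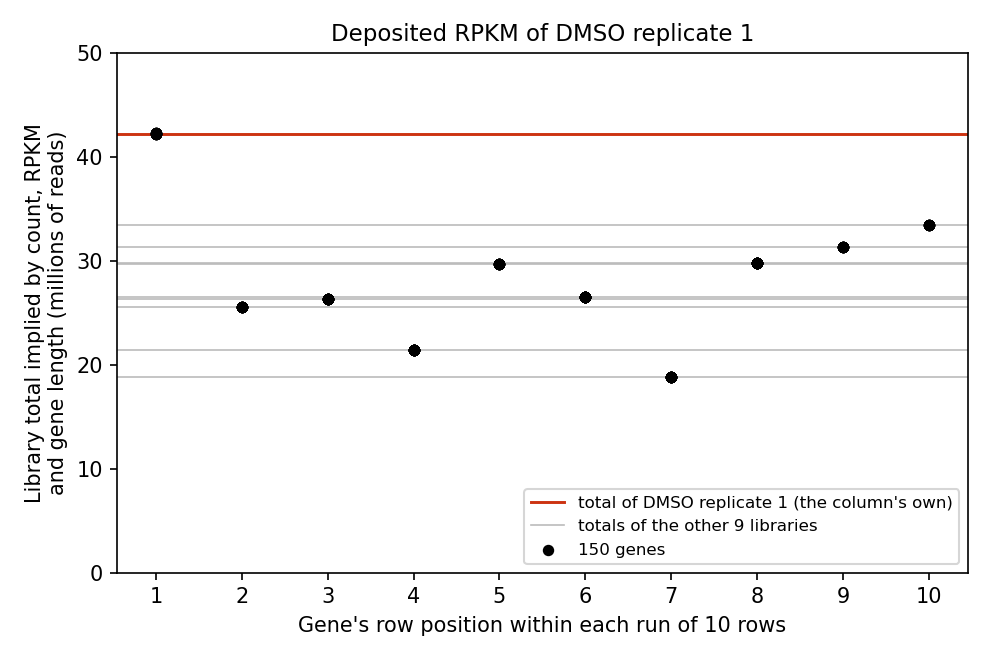
Library total implied by the count, the deposited RPKM and the recovered gene length for 150 genes in the column of DMSO replicate 1 (y axis), against the position of the gene's row within each run of 10 rows (x axis). Points fall on the total of DMSO replicate 1 (42253397 reads, red line) at the first position only, and on the totals of the other 9 libraries (grey lines) at the other positions.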

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

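Of the tests in this part, the one of treatment as the source of the first component was chosen after the scores had been seen. The measures of read concentration were also chosen after the data were seen. A check for a library far from the other 4 of its group was made on 24 sets of 5 values and singled out 3, and chance alone singles out about 1 in 20.

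DMSO replicate 2 had a first component score of 86.2, far above the other 4 DMSO libraries, and it lay with rotenone replicates 3, 4 and 5 above the widest gap on that axis. Library depth is argued against: with every library thinned to the smallest total, the component still held 36.8% of the variance, against 37.5% before. Gene length is argued against likewise, since removing each library's trend with length left 37.6%. Treatment alone did not order the libraries on this axis: 3 libraries (DMSO replicate 2 and rotenone replicates 1 and 2) lay across the gap from most of their group. The cut-off of 3 libraries was written after the scores were seen, so this describes the axis and is no independent test. Other differences between the skin samples were not tested, since no gene names could be assigned and the labels give no batch.

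Rotenone replicate 4 was singled out with 19.3% of its reads on the 10 most abundant genes, above the 14.0% to 15.2% of the other 4 rotenone libraries. Without it the rotenone minus DMSO difference in the share on the 100 most abundant genes was 3.94 percentage points, against 5.54 with it, and the exact permutation p was 0.016. The 10 most abundant genes as the whole source of that difference cannot be told apart from a wider one: genes ranked 11 to 100 still took 2.47 points more in rotenone libraries, with an exact p of 0.056. A bias towards short genes is not decided either, since the longer 50 of the 100 genes took 3.40 points more (exact p = 0.063) and the shorter 50 took 2.14 points more (exact p = 0.0079). A response of skin to rotenone stays open as a hypothesis, with no test that could part it from other differences between the samples.

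DMSO replicate 4 was singled out for Nfu_g_1_006811, with a log2 CPM of 3.14, the lowest of the DMSO libraries.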

How the results depend on the processing

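The count of 0 genes was also found in 18 of 27 alternatives. With edgeR these were RLE and upper-quartile scaling, both other count filters, robust=FALSE and each library left out. The other 3 were limma-trend fits on deposited RPKM, whose library totals were misassigned in the genes checked. It became 231 with DESeq2, 26 with limma voom and quality weights, 1 with limma voom, 1 with 1 surrogate variable, 18 with library-size scaling and 23 at an adjusted p under 0.1. Of the alternatives added after the data were seen, RPKM recomputed with each library's own total gave 17, DESeq2 with TMM factors and the edgeR filter 232 and 2 surrogate variables 1. Scaling and filter therefore do not account for the gap between DESeq2 and edgeR, and the cause of the other moves was not tested. Library-size scaling moved the median log2 fold change by 0.14, from 0.03 to -0.11, and all 18 of its calls were lower. The share of DESeq2 calls that were lower was 75.3% with its own size factors and filter. It was 65.1% with TMM factors and the edgeR filter, which were changed together. DESeq2 called 133 to 626 genes with a library left out, and 105 genes were called with all 10 libraries and in every set of 9. Unadjusted counts ran from 735 (deposited RPKM with a mean of at least 1) to 2219 (voom with quality weights), and from 1014 to 1904 with a library left out. The between-group share of distance ran from 10.0% to 19.7% with a library left out and was highest without DMSO replicate 2, where its exact permutation p was 0.11. No alternative brought its p under 0.05. The difference in reads on the 100 most abundant genes ran from 3.94 to 6.26 percentage points with a library left out, and its p stayed under 0.05 in these and with the 10, 50 or 500 most abundant genes, the genes most abundant in DMSO libraries or each library's own 100. The single most abundant gene took a lower mean share in rotenone libraries (exact permutation p = 0.70). All 4 named genes kept their direction in all 26 alternatives, but not their size or call. They were picked for the smallest p in these libraries, so a kept direction largely follows from the choice. Log2 fold changes ran from -2.25 to -1.90 for Nfu_g_1_021435, from -1.77 to -0.73 for Nfu_g_1_004690, from 0.49 to 0.92 for Nfu_g_1_006811 and from 0.48 to 1.02 for Nfu_g_1_003916. They passed the threshold in 6, 5, 3 and 3 alternatives. Adjusted p reached 0.44 (first) and 0.87 (other 3) with deposited RPKM, and at most 0.27 otherwise. The planned gene list alternatives were not run, as no list matched. No paired analysis was possible, as the labels pair no libraries.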

Other observations

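Of the tests in this part, the count of splits for the 0 genes past the edgeR threshold was chosen after the result was seen. The largest rises among the abundant genes were shared by 4 of the 5 rotenone libraries. The 10 genes of the 100 most abundant that gained most in mean share took 11.3% to 17.1% of reads in rotenone replicates 2 to 5, 4.82% in rotenone replicate 1 and 4.87% to 8.25% in the DMSO libraries. These 10 genes were picked for their difference in these libraries, so the values describe the libraries and test nothing.

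DESeq2 called 231 genes where edgeR called 0. Of the 231 genes, 105 were also called in each of the 10 sets of 9 libraries, and the count ran from 133 to 626 over these sets. In 76.2% of the 231 all 5 rotenone values lay on one side of the 5 DMSO values, which describes genes called for a group difference and tests nothing. Chance assignment was not excluded: among 100 of the 126 splits into 5 and 5, 11 gave at least 231 DESeq2 calls, the real one included, and the highest other gave 882. That split placed DMSO replicates 1, 2 and 5 with rotenone replicates 1 and 5. These 5 had the lowest scores on the second component (-43.7 to -16.5, with DMSO replicate 3 next at -13.1). The split was the highest of those drawn, and whether its count reflects a structure among the libraries was not tested. In simulated data DESeq2 made 26 false calls and edgeR 4.

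The same 100 splits were counted for the other results. For the edgeR count past the threshold, where the real value was 0, all 100 splits had to give at least as many, so this count can show nothing. The highest other gave 1. For genes at an adjusted p under 0.1, where the real split gave 23, 4 of the 100 drawn splits gave as many, the real one included, and the other 3 gave 89, 143 and 209. This met the rule written beforehand for arguing against chance assignment, under 5 of every 100 splits. It is 1 of 5 such counts, with no adjustment and not all of the 126 splits drawn, so chance assignment is not taken as excluded. For genes at an unadjusted p under 0.05, 23 splits reached the real 1412 and the highest other gave 3341. For genes whose groups did not overlap, 9 splits reached the real 327 and the highest other gave 623, so that chance is not excluded for either.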
